A study of Arabidopsis thaliana with 12 samples.

How the data were processed

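RNA from roots of 10-day-old Arabidopsis thaliana plants (Columbia) was measured on one-colour Affymetrix ATH1 arrays. Both genotypes were compared, wild type and chl1-5, a mutant of the nitrate transporter CHL1, each before nitrate (T0) and after 0.5 h in 25 mM KNO3 (T0.5). Each of the 4 groups had 3 arrays, 12 in all. Per the labels' protocols, plants grew with 12.5 mM ammonium succinate as the only nitrogen source, both genotypes in separate areas of one mesh, and spent 3 h in the same nitrogen source at pH 5.5 before washing. The roots were then collected, or moved for 30 min to medium in which KNO3 took the place of the ammonium salt. About 900 seedlings from 9 vessels were pooled for each replicate, and 6 µg of total RNA was labelled per array. The step from T0 to T0.5 therefore also holds the loss of ammonium succinate and a transfer, and no array of plants moved to a chloride salt was analysed here.

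The deposited values are fluorescence intensities on a linear scale, summarized by the authors to 1 signal per probe set with MAS5, per the submitters' processing notes. The version was not given in the sources used here. The mean of every array after trimming 2% at each end lay between 499.4 and 500.6, so the authors had already scaled the arrays, and no detection calls were used. Array medians lay between 175.9 and 195.4, and array maxima between 20559 and 28753. The table held 22810 probe sets, of which 64 were controls and left out. No array was a copy of another, and 2 values were listed at 0. With 3 arrays per group, the number of arrays limits the precision.

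Probe sets took their gene names from the platform annotation table, matched by gene number to the TAIR10.1 gene table, which was used for names and for which genes neighbour each other. Of 22746 probe sets, 13513 had 1 gene, 503 had several and stayed unnamed, and 8730 were not listed in that table and are reported by probe set. Of the 13513, 13436 matched, at 13355 loci. Only 42 of the 290 genes on the lists chosen before the data were examined had a named probe set, and CHL1 was not among the named genes, so the planned check of the mutated gene was not made.

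Signals were raised to a floor of 0.1 and put on the log2 scale. Probe sets at or above the 40th percentile of their array in at least 3 arrays were tested, 14291 in all. One limma model (limma 3.58.1, R 4.3.3; lmFit, contrasts.fit and eBayes with trend) fitted the 4 group means over all 12 arrays. It gave the nitrate response of each genotype, their difference, the genotype difference at each time and the mean response over both genotypes. Tests were two-sided, and a probe set was called at a Benjamini-Hochberg adjusted p under 0.05. Adjusted p-values below are limma's unless another test is named. A gene is called dim in a group when its signal was under the 40th percentile on all 3 arrays there, and a fold against such a group rests on weak signals.

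Gene lists with at least 4 tested genes were tested with camera (limma) at its preset correlation of 0.01 and again with an estimated correlation, adjusted over 25 lists within each of 5 comparisons. The lists chosen before the data were examined that reached this size were nitrate response regulators, the pentose phosphate pathway, touch and early stress response, and sugar starvation. The others are families defined by gene symbols, chosen after the name table was seen and before any comparison was computed. A mitochondrial gene that the plastid pattern had taken in was removed later. The size of the chl1-5 response was described over probe sets called in the mean response, a comparison independent of the genotype difference in this balanced design, and tested with fry (limma). It was also tested with an exact permutation of the genotype labels within each time (400 relabelings, median difference of the set, two-sided), which leaves the mean response of each probe set as it is. The permutation was repeated with labels swapped only within replicate numbers (64 relabelings). These tests and the sets limited to a mean response of at least 2-fold and 4-fold were chosen after the data were seen.

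Genes were named by a rule fixed before the data were examined. It took, among probe sets of 1 locus that passed with no overlap between both groups' arrays, the 12 largest rises and the 12 largest falls of the wild-type response, and the 8 and 8 of each other comparison, without the overlap condition for the difference of responses. Chance alone gives no overlap of 3 against 3 arrays with a share of 0.1. Members of the fixed lists and loci next to CHL1 were named as well. A locus with several probe sets was represented by the brightest.

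The replicate numbers come from the sample titles, and each marks an independent experiment per the labels. They pair the arrays. All 18 pairs of arrays with the same number in different groups deviated together from their group means (r from 0.21 to 0.77 across probe sets), the highest r between different numbers was -0.01, and all 12 arrays matched best with their own number. The fit was repeated with the replicate number as a fixed block, as chosen before the data were examined. It was also repeated with quantile normalization, median scaling, no filter, a filter at the 60th percentile, a pseudocount of 22.05 (the median over arrays of the 20th percentile), no variance trend, array weights, fits of only the 2 groups compared, and each array left out in turn. Leaving out all 4 arrays of a replicate number was added after the data were seen.

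The code was tested on simulated data built from these arrays, with 200 of 14291 probe sets changed in 5 runs. In the wild-type response, 80.4% of changes of 1 on the log2 scale and 98.8% of changes of 2 were recovered, with 4.74% false calls. In the difference of responses, 50% of differences of 1 were recovered. Tables were prepared and figures drawn with Python 3.11.15 (pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, matplotlib 3.10.9).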

Results

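Root transcript levels were recorded on 12 arrays, 3 for each combination of genotype (wild type and the nitrate transporter mutant chl1-5) and time (before nitrate, T0, and after 30 min in 25 mM nitrate, T0.5). Arrays of one group differed little, with a median SD between 0.16 and 0.18 on the log2 scale over the 14291 probe sets tested. As signs of RNA quality, the 3'/5' signal ratio of the GAPDH control probe sets lay between 0.86 and 1.38 and that of the ubiquitin probe sets between 1.68 and 2.24. The GAPDH ratios of the wild-type T0 arrays (0.86 to 1.14) lay below those of the chl1-5 T0.5 arrays (1.19 to 1.23). The actin ratio was wider, from 9.72 to 18.4, and its highest value belonged to the chl1-5 T0 array of replicate 3. The design asks which root genes answer nitrate within 30 min, and which of these answers depend on CHL1. Below, a response or answer to nitrate means the change from T0 to T0.5. It also holds the loss of ammonium succinate and a transfer, which these arrays cannot separate from nitrate.

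In wild-type roots transcripts of the 4 nitrate response regulators measured, of PGM and of 2 of 4 pentose phosphate genes rose from T0 to T0.5. Single genes such as EXPA9 fell. PGM (AT1G78050), a phosphoglycerate mutase of glycolysis, rose 26.4-fold (log2 4.72, SE 0.14, n = 3 arrays per group, adjusted p = 6.86e-10), from a mean signal of 209 ± 19.9 to 5502 ± 251 (SD). AT1G80380, a glycerate kinase, rose 26.2-fold (log2 4.71, SE 0.22). HHO2 and HHO3, related transcription factors that answer nitrate, rose 4.59-fold and 5.60-fold (SE 0.19 and 0.25 on the log2 scale). EXPA9, an expansin, fell 3.21-fold (log2 -1.68, SE 0.11, adjusted p = 1.19e-06).

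**Figure D1:**
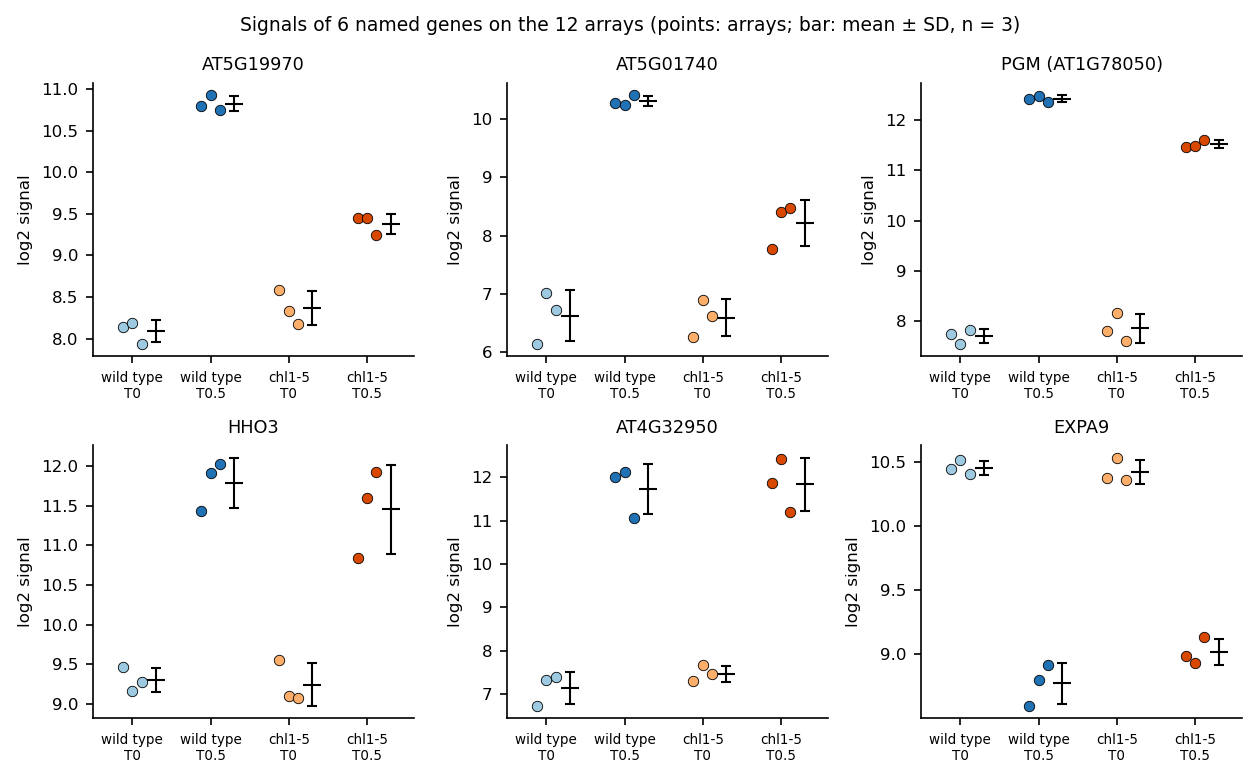
The log2 signal (vertical axis) of 6 named genes is shown in each of the 4 groups (horizontal axis), with a point for each array and a bar for the mean ± SD of 3 arrays. AT5G19970 and AT5G01740 rose less in chl1-5 (log2 1.02 and 1.62) than in wild type (2.74 and 3.68). Without the replicate block only the difference of AT5G19970 passed limma, and with the block that of AT5G01740 passed too (adjusted p = 0.00591).

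Among the other named genes with the largest rises in wild type, AT2G48080 gained 5.23 (SE 0.29), AT3G07350 4.56 (SE 0.35), AT5G01740 3.68 (SE 0.25) and AT1G49500 3.39 (SE 0.18) on the log2 scale. Probe sets without a named gene were left out of this ranking, among them 264859_at, which rose by 4.34 (SE 0.12). The protein phosphatase gene AT4G32950 of the PP2C family rose 24.0-fold (log2 4.59, SE 0.32), and the thaumatin family gene AT4G36010 rose 12.8-fold (log2 3.67, SE 0.21). AT5G28610 rose by 3.79 (SE 0.78, adjusted p = 0.0124). For AT5G10210 (log2 7.22, SE 1.04), HHO1 (log2 6.86, SE 1.01), a relative of HHO2, and AT5G62720, which encodes an HPP-type membrane protein (log2 3.25, SE 0.71), the fold rests on dim signals at T0.

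The largest falls in wild type were smaller than the largest rises. CYP718, a cytochrome P450 gene, fell by 3.26 (SE 0.84, adjusted p = 0.0420) and AT2G43890 by 3.08 (SE 0.80, adjusted p = 0.0432), both near the threshold. AT4G17670 fell by 2.01, AT1G64590 by 1.89, AT1G53620 by 1.78, AT4G18630 by 1.61, AT5G01720 by 1.59 and AT1G57630 by 1.57 on the log2 scale, with SE from 0.23 to 0.40. The kinase family gene AT1G21590 fell 3.03-fold (SE 0.16 on the log2 scale). The calcium-binding EF-hand gene AT1G21550 fell by 2.02 (SE 0.49) and AT3G59850 by 1.72 (SE 0.39). AT2G43890, AT1G21550 and AT3G59850 were dim at T0.5. CYP718, AT1G53620 and AT4G18630 had mean signals of only 43.4, 77.1 and 87.6 at T0.5, so their falls rest on weak signals too.

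In all, 797 probe sets changed in wild type, 491 higher and 306 lower, and 383 of them at least 2-fold (288 higher, 95 lower). Genes with a name made up 425 of the 797. The split moved with the scaling, to 552 higher and 220 lower under median scaling and to 527 and 242 under quantile normalization. With the replicate number as a block, 1690 probe sets passed (819 higher, 871 lower), among them all 797. Without 1 of the 6 arrays the count was 482 to 530, except 927 without the T0.5 array of replicate 1, and without all arrays of replicate number 1, 2 or 3 it was 882, 177 and 391.

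Of the nitrate response regulators, 4 of the 28 listed genes had a named probe set and all 4 rose in wild type, HHO1, HHO2, HHO3 and NRG2 (log2 0.57, SE 0.12), over all genes and adjusted over the list alone. Their median rise was 2.34 (camera adjusted p = 3.15e-09, and adjusted p = 0.0394 with an estimated correlation). Of the 4 pentose phosphate genes tested, the 6-phosphogluconate dehydrogenases PGD1 (log2 1.89, SE 0.11) and PGD3 (log2 2.23, SE 0.20) rose, also adjusted over the list alone. PGD2 and the transaldolase TRA1 stood at -0.02 and -0.01 (SE 0.11 each). The list's median was 0.94 (camera adjusted p = 4.78e-04, but adjusted p = 0.0761 with an estimated correlation).

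None of the 5 touch and early stress genes passed limma over all genes in wild type, with 1 at an unadjusted p under 0.05. Adjusted over the list alone, 1 passed, CML38, a calmodulin-like gene (4.58-fold, SE 0.63 on the log2 scale, adjusted p = 0.0655 over all genes, 0.0142 with the replicate block). Their median was 0.78 (camera adjusted p = 0.0344, but adjusted p = 0.734 with an estimated correlation). The 5 sugar starvation genes had a median of 0.13 in wild type (camera adjusted p = 0.147), and none of them passed limma, with 1 at an unadjusted p under 0.05. Of the listed genes too few for a test, GH3.5, an auxin-conjugating enzyme, fell by 0.58 (SE 0.11, adjusted p = 0.00725), and EXP7, an expansin of root hair cells, fell by 0.79 (SE 0.17, adjusted p = 0.0172). The sulfate assimilation gene APS3 stood at 1.07 (SE 0.36, adjusted p = 0.121, 0.00898 with the replicate block). The nitrate transporter gene NRT2.5 stood at -0.66 (SE 0.25, adjusted p = 0.173). For shoot tissue, the listed marker RCA stood at 0.03 (SE 0.12).

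**Figure D2:**
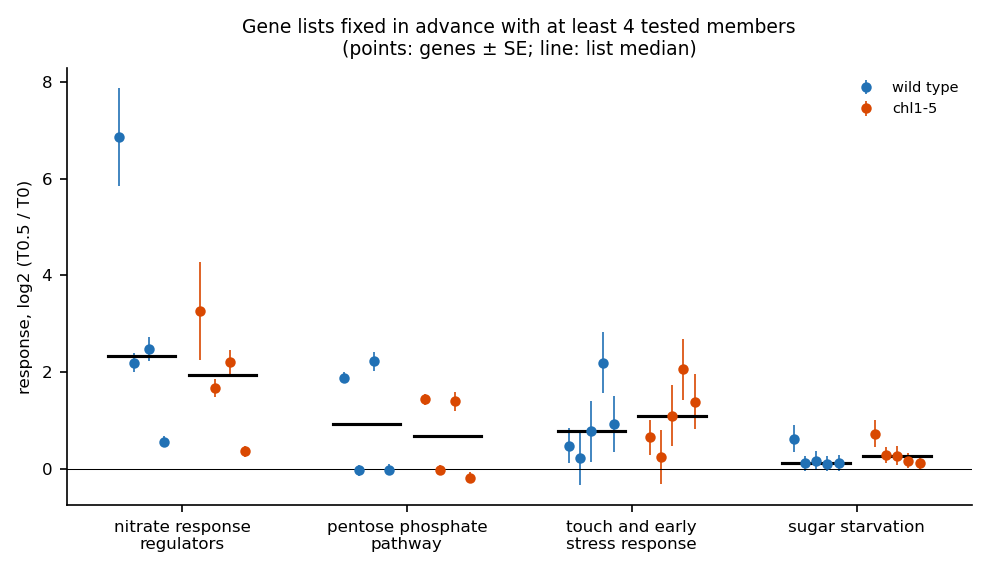
The log2 response to nitrate (vertical axis) of each tested gene of the 4 lists fixed in advance (horizontal axis) is shown as a point with its SE, wild type in blue and chl1-5 in orange, and a line marks each list's median. The 4 nitrate response regulators had medians of 2.34 and 1.94, while 2 of the 4 pentose phosphate genes, PGD1 and PGD3, rose in each genotype.

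Roots of chl1-5 answered nitrate with many of the same genes. AT4G32950 rose 20.6-fold (log2 4.37, SE 0.32, n = 3 arrays per group, adjusted p = 7.43e-06), AT2G48080 14.4-fold (log2 3.85, SE 0.29), PGM 12.7-fold (log2 3.67, SE 0.14) and AT3G07350 10.4-fold (log2 3.38, SE 0.35). AT5G28610 rose by 3.49 (SE 0.78). EXPA9 fell 2.65-fold (log2 -1.40, SE 0.11), AT1G21590 3.15-fold (log2 -1.65, SE 0.16) and AT5G01720 2.65-fold (log2 -1.41, SE 0.24).

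Among the genes dim at T0 in chl1-5 that rose there were AT5G10210 (log2 4.98, SE 1.04), EXLA3, an expansin-like gene (log2 4.53, SE 0.97, adjusted p = 0.0231), AT5G62720 (log2 4.12, SE 0.71) and AT5G28610. In wild type EXLA3 stood at 3.35 (adjusted p = 0.0692, 0.0323 with the replicate block), and its responses did not differ by the test (difference 1.18, SE 1.38, adjusted p = 1.00). Further falls in chl1-5 were those of AT1G21550 by 2.08, dim at T0.5, AT1G64590 by 1.37, AT4G17670 by 1.31, AT1G66930 by 1.31 and AT4G18630 by 1.25 on the log2 scale, with SE from 0.16 to 0.49. CYP718 stood at -0.96 in chl1-5 (SE 0.84, adjusted p = 0.634), and its difference from wild type did not pass (SE 1.19, adjusted p = 1.00).

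In total 552 probe sets changed in chl1-5, 387 higher and 165 lower, 256 of them at least 2-fold (223 higher, 33 lower), and 300 had a name. Under median scaling 410 were higher and 123 lower, and under quantile normalization 388 and 150. With the replicate block 1415 passed (744 higher, 671 lower), among them all 552, and in a fit of the chl1-5 arrays alone 336 passed (266 higher, 70 lower). Without 1 of the 6 arrays the count was 260 to 348, except 854 without the T0.5 array of replicate 1, and without replicate number 1, 2 or 3 it was 800, 74 and 203.

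Of the nitrate response regulators, HHO2 (log2 1.68, SE 0.19) and HHO3 (log2 2.21, SE 0.25) rose in chl1-5 over all genes, and all 4 rose adjusted over the list alone. HHO1 stood at 3.26 (SE 1.01, adjusted p = 0.111, 0.0468 with the replicate block) and NRG2 at 0.37 (SE 0.12, adjusted p = 0.115, 0.0498 with the block). The list's median was 1.94 (camera adjusted p = 8.84e-07, but adjusted p = 0.103 with an estimated correlation). PGD1 (log2 1.44, SE 0.11) and PGD3 (2.65-fold, SE 0.20 on the log2 scale) rose, in all 2 of 4 pentose phosphate genes over all genes and adjusted over the list alone. The median of that list was 0.69 (camera adjusted p = 0.0117, but adjusted p = 0.263 with an estimated correlation).

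The 5 touch and early stress genes had a median of 1.11 in chl1-5 (camera adjusted p = 0.0180, but adjusted p = 0.657 with an estimated correlation), and none passed limma over all genes, with 2 at an unadjusted p under 0.05. Adjusted over the list alone 1 passed, CML38 (log2 2.07, SE 0.63, adjusted p = 0.102 over all genes, 0.0233 with the replicate block). The 5 sugar starvation genes had a median of 0.28 (camera adjusted p = 0.0353, but adjusted p = 0.657 with an estimated correlation), with none passing limma and 1 at an unadjusted p under 0.05. GH3.5 fell by 0.44 (SE 0.11) and EXP7 by 0.73 (SE 0.17) in chl1-5.

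Set side by side, 330 probe sets rose in both genotypes, of 491 and 387, where 13.3 would be shared if the lists were independent. In the other direction 110 fell in both, of 306 and 165, where 3.53 would be shared. The responses share no arrays, though arrays with the same replicate number deviate together and both responses use the same estimate of each probe set's spread. Across all probe sets tested they correlated with Pearson's r = 0.87 and Spearman's rho = 0.67, a relation across genes, which are not independent replicates. No probe set was called in opposite directions. Of the 161 probe sets called higher in wild type alone, 159 had the same sign in chl1-5 and 126 an unadjusted p under 0.05 there, and of the 196 called lower in wild type alone all 196 had the same sign and 144 an unadjusted p under 0.05. A call in wild type alone is thus not by itself a difference between genotypes.

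**Figure D3:**
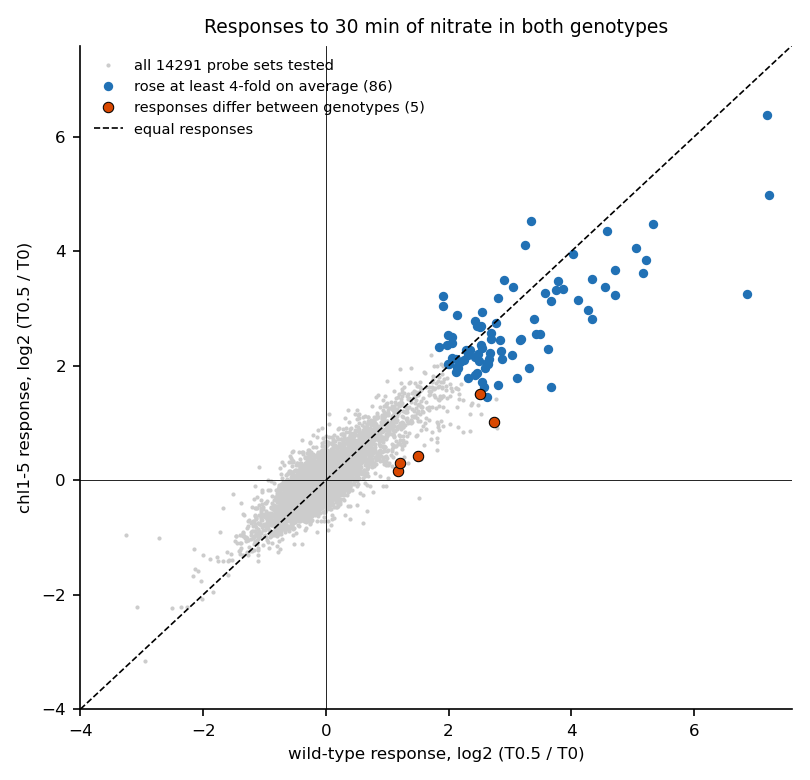
The nitrate response in chl1-5 (vertical axis, log2) is plotted against that in wild type (horizontal axis, log2) for all 14291 probe sets tested (grey). Blue marks the 86 that rose at least 4-fold on average, and a dashed line marks equal responses. Orange marks the 5 called in the difference of responses, a count for which chance is not excluded. Of the 86, 65 lie below the line of equal responses.

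The mean response over both genotypes called 1998 probe sets, 917 higher and 1081 lower (45.9% higher). This split moved with the scaling, to 1045 higher and 691 lower under median scaling (60.2% higher) and to 971 and 884 under quantile normalization (52.3% higher), while with the replicate block 3452 passed (1330 higher, 2122 lower). Without replicate number 2 or 3 the count was 501 and 869.

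Over the 917 probe sets that rose on average, the median response was 0.86 in wild type and 0.77 in chl1-5 on the log2 scale. The median difference was -0.07, and 61.7% of the probe sets had the smaller response in chl1-5. An exact permutation of the genotype labels within each time gave p = 0.645, and p = 0.375 within replicate numbers (fry p = 0.291). Over the 1081 that fell, the medians were -0.51 and -0.46, the median difference was 0.06 and the exact permutation gave p = 0.405, and p = 0.156 within replicate numbers (fry p = 0.395). Among probe sets that rose at least 4-fold on average the median difference was larger, -0.42 over 86, with 65 (75.6%) smaller in chl1-5, and medians of 2.68 and 2.46. The exact permutation gave p = 0.300, and p = 0.250 within replicate numbers (fry p = 0.0629, and p = 0.0151 with the replicate block), so the smaller rise of the set passed only by fry with the block. Of the 84 probe sets that fell at least 2-fold on average, 71 (84.5%) fell less in chl1-5, with a median difference of 0.22 (exact permutation p = 0.360, and p = 0.250 within replicate numbers; fry p = 0.220, and p = 0.0334 with the block).

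The response to nitrate differed between genotypes, by the test of the difference itself, for 5 probe sets, all with the weaker rise in chl1-5. AT5G19970 rose 6.66-fold in wild type (log2 2.74, SE 0.13) and 2.02-fold in chl1-5 (log2 1.02, SE 0.13), a difference of -1.72 (SE 0.18, n = 3 arrays per group, adjusted p = 0.00679). Its mean signal went from 273 ± 24.4 to 1815 ± 116 (SD) in wild type and from 332 ± 47.5 to 669 ± 53.9 in chl1-5. The others had no named gene and fell outside the naming rule, so they were chosen after their values were seen. Probe set 258350_at differed by -1.09 (adjusted p = 0.0222), 246216_at by -1.02 (adjusted p = 0.0162), 255230_at by -1.01 (adjusted p = 0.0162) and 249710_at by -0.91 (adjusted p = 0.0222).

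In all, 277 of 14291 probe sets had an unadjusted p under 0.05 for the difference, below the share of 0.05 that chance would give. The fit without the block counts deviations shared by a replicate number as spread. The low share therefore does not show that the genotypes responded alike. Of these 277, 159 were lower and 118 higher in chl1-5, and no rise that was larger in chl1-5 passed limma. With the replicate block 17 passed, all with the lower response in chl1-5, among them AT5G01740 (difference -2.05, SE 0.35, adjusted p = 0.134, 0.00591 with the block) and AT1G80380 (-1.47, SE 0.31, adjusted p = 0.305, 0.00724 with the block). PGM differed by -1.05 (SE 0.19, adjusted p = 0.233) and HHO1 by -3.60 (SE 1.43, adjusted p = 1.00), neither passing with the block. Without 1 array the count was 1 to 4, and it was 0 without any of the replicate numbers 1, 2 or 3.

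As a list, the nitrate response regulators had the weaker rise in chl1-5 (median difference -0.40, camera adjusted p = 0.00145, but adjusted p = 0.191 with an estimated correlation), though none of the 4 passed limma singly or adjusted over the list alone. The pentose phosphate list differed by a median of -0.30 (camera adjusted p = 0.00145, but adjusted p = 0.186 with an estimated correlation). Its members PGD1 (-0.44) and PGD3 (-0.83) were the 2 that passed adjusted over the list alone, and neither passed over all genes. The touch and early stress genes had a median difference of 0.17 (camera adjusted p = 0.861) and the sugar starvation genes of 0.10 (camera adjusted p = 0.854).

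Before nitrate the genotypes differed at 4 probe sets, and all 4 also differed at T0.5, on other arrays. ATKDSA2 (AT1G16340), a synthase of the cell wall sugar acid KDO, was lower in chl1-5 by 3.43 (SE 0.44, n = 3 arrays per group, adjusted p = 0.0207) at T0 and by 3.63 (SE 0.44, adjusted p = 0.00337) at T0.5 on the log2 scale, with mean signals of 306 ± 10.6 and 304 ± 10.7 (SD) in wild type against 34.6 ± 21.6 and 24.6 ± 2.82 in chl1-5, where it was dim. QQS (AT3G30720), an orphan gene that affects starch content, was higher in chl1-5 by 2.92 (SE 0.39, adjusted p = 0.0260) at T0 and 2.75 (SE 0.39, adjusted p = 0.0115) at T0.5. Its mean signal was 272 ± 49.0 and 232 ± 19.1 in chl1-5 against 37.9 ± 15 and 38.4 ± 22 in wild type, where it was dim. Neither responded to nitrate in either genotype by the test.

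Probe sets 264348_at (log2 -6.37 at T0, SE 0.59, adjusted p = 0.00201; -5.99 at T0.5) and 264371_at (log2 -6.04 at T0, SE 0.63, adjusted p = 0.00331; -6.22 at T0.5), both unnamed here and chosen after their values were seen, were lower in chl1-5. 264348_at was dim in chl1-5 at T0 (mean signal 26.8), so the size of its difference there rests on weak signals. In chl1-5 264371_at had mean signals of 69.5 at T0 and 62.1 at T0.5, and 264348_at one of 125.6 ± 92.1 (SD) at T0.5. The sizes of these differences rest on weak signals too. In fits of only the 2 groups compared, ATKDSA2 at T0 and QQS at both times no longer passed, and the 2 unnamed probe sets were left at T0. With the filter at the 60th percentile ATKDSA2 did not pass at T0 and QQS was not tested, which left the same 2; without 1 array the count was 2 or 3, and without replicate number 1, 2 or 3 it was 0, 2 and 1.

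**Figure D4:**
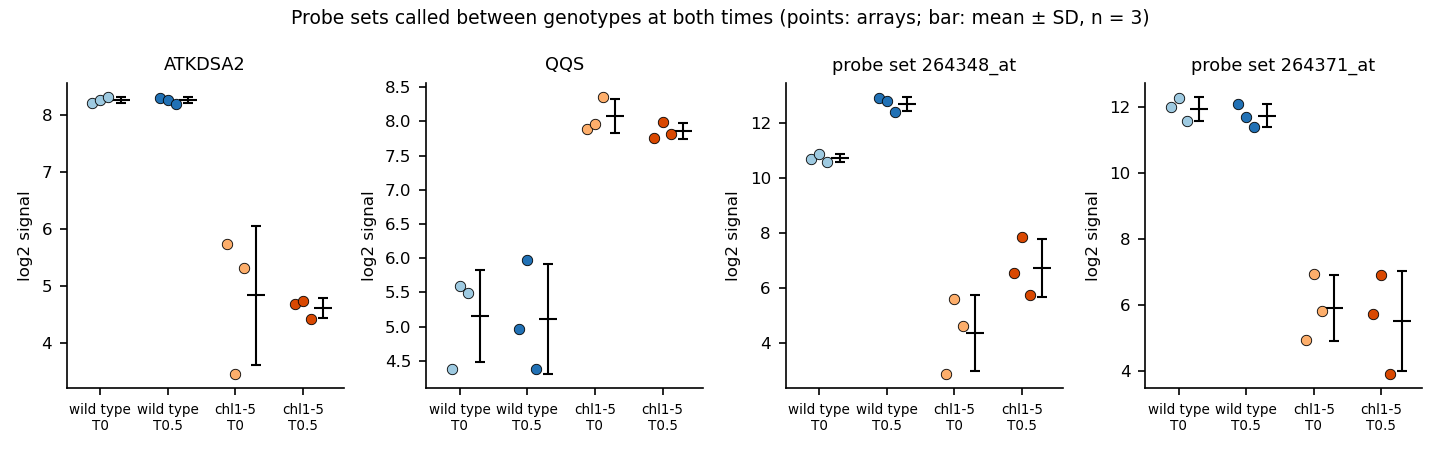
The log2 signal (vertical axis) of the 4 probe sets that differed between genotypes at both times is shown for each of the 4 groups (horizontal axis), with a point for each array and a bar for the mean ± SD of 3 arrays. ATKDSA2 had means of 306 and 304 in wild type against 34.6 and 24.6 in chl1-5 as linear signals, QQS lay higher in chl1-5, and the 2 unnamed probe sets were lower in chl1-5 by 5.99 to 6.37 on the log2 scale.

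CHL1 was not among the named genes, so its signal was not examined by name here. The chl1-5 lesion is a deletion at CHL1, so loci beside it were examined for a shared loss. Between AT1G11900 and AT1G12300, 28 loci had a named probe set and 17 were tested. Probe sets without a named gene were left out of this check, so it does not cover the whole window. Among those left out were 264348_at and 264371_at, lower in chl1-5 at T0 (log2 -6.37 and -6.04). Their probe set numbers lie among those of the window's named probe sets. Whether they measure CHL1 or a locus beside it was not tested, so a loss in this window is not excluded. None of the 17 named loci tested differed between genotypes by limma at either time, and 0 had an unadjusted p under 0.05. Their log2 differences lay between -0.17 and 0.37 at T0 and between -0.30 and 0.36 at T0.5.

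After 30 min of nitrate, 31 probe sets were lower and 1, QQS, was higher in chl1-5 than in wild type. AT5G01740 was 4.26-fold lower (log2 -2.09, SE 0.25, n = 3 arrays per group, adjusted p = 0.00310), at a mean signal of 304 ± 76.0 against 1266 ± 74.7 (SD). AT1G72220, a RING-type ubiquitin ligase gene, was 2.73-fold lower (log2 -1.45, SE 0.19, adjusted p = 0.00688) and AT5G19970 2.72-fold lower (log2 -1.44, SE 0.13, adjusted p = 4.25e-04). PGM was 1.87-fold lower (log2 -0.90, SE 0.14, adjusted p = 0.0139), at 2942 ± 151 against 5502 ± 251, and AT5G51830, a fructokinase-type sugar kinase gene, 1.83-fold lower (log2 -0.88, SE 0.13, adjusted p = 0.0139).

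AT5G53750 (log2 -1.31, SE 0.20, adjusted p = 0.0142) and AT1G73920 (log2 -0.99, SE 0.14, adjusted p = 0.00840) were lower in chl1-5 too. Of the 31 lower probe sets, 28 were called higher in the mean nitrate response, where 1.99 would be if both lists were independent, and 10 had a name. Both lists use the same estimate of each probe set's spread, so they are not fully independent. Of the 32 in all, 13 differed at least 2-fold. With the replicate block 60 passed (3 higher, 57 lower), among them PGD1 (-0.45, adjusted p = 0.418, 0.00909 with the block) and PGD3 (-0.88, adjusted p = 0.209, 0.00484 with the block). Without 1 of the 6 arrays the count was 11 to 21, and without replicate number 1, 2 or 3 it was 12, 3 and 2.

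At T0.5 the pentose phosphate list was lower in chl1-5 (median -0.28, camera adjusted p = 3.02e-04, but adjusted p = 0.0577 with an estimated correlation), and 2 of its 4 genes, PGD1 and PGD3, were lower adjusted over the list alone. The nitrate response regulators had a median of -0.36 (camera adjusted p = 0.00123, but adjusted p = 0.196 with an estimated correlation), with no member passing singly. The touch and sugar starvation lists were not called at either time. At T0 the regulators stood at a median of 0.06 (camera adjusted p = 0.631) and the pentose phosphate genes at -0.01 (camera adjusted p = 0.922).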

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

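The tests chosen after the results were seen were the counts over other splits of the arrays, also within replicate numbers, the check for a mislabelled array, the plastid list without 1 replicate number, the nuclear photosynthesis comparison, the exact permutations of genotype labels and the limits of 2-fold and 4-fold. The results here drew attention because the response to nitrate differed between wild type and chl1-5 by the test of the difference itself.

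AT5G19970 had the weaker rise in chl1-5, by -1.72, and the unnamed probe sets 258350_at (-1.09), 246216_at (-1.02), 255230_at (-1.01) and 249710_at (-0.91) did so as well. Among the gene lists, the difference was -0.40 at the median for the nitrate response regulators, -0.30 for the pentose phosphate pathway, -0.0933 for the glycolysis enzymes and 0.25 for the plastid-encoded genes. With an estimated correlation none of these lists passed (adjusted p = 0.191, 0.186, 0.186 and 0.910). Of 100 splits of the 12 arrays with the same layout, the real one included, 9 gave at least as many as the 5 probe sets called and the highest other gave 14, so chance cannot be excluded as the source of a count of this size. Among 32 regroupings that swap genotypes only within replicate numbers, 6 gave at least 5 (highest other 10), and with the replicate block 3 gave at least the 17 called (highest other 25), so chance is not excluded there either. For the mean response, 1 of 100 splits, the real one, reached 1998 calls and the highest other gave 176, so chance is argued against there. Swaps of genotype leave the mean response as it is, so its 32 regroupings within replicate numbers were not those above. The highest other of these gave 9 against 1998 (45 against 3452 with the block).

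The comparisons of 3 against 3 arrays have 10 splits, too few for a share under 0.05. The highest count among the other splits was 0 against 797 in the wild-type response, 0 against 552 in the chl1-5 response, 2 against 4 between genotypes at T0 and 11 against 32 at T0.5. Among the 4 splits that, like the real one, part all pairs of a replicate number, the highest other was 0 in each. The splits that keep a pair together on one side differ from it in also setting replicate numbers against each other.

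The first pattern is a smaller rise in chl1-5 of the probe sets that rose at least 2-fold on average, 226 of 340 with a median difference of -0.17 (exact permutation p = 0.535, and p = 0.250 within replicate numbers; directional fry p = 0.230, and p = 0.164 with the block). A compressed signal on the chl1-5 T0.5 arrays is argued against, since the SD across unresponsive probe sets was 0.992 of that in wild type (0.98 to 1.01 by replicate number), above the ratio of 0.878 between the median responses. A single weak replicate number as the only source is argued against too, since the median difference was below 0 in each. It was -0.34, -0.13 and -0.14 in replicate numbers 1, 2 and 3. The difference was largest in number 1, so a larger share from that number is not excluded. Exact permutation within replicate numbers gave p = 0.250 for the 86 that rose at least 4-fold (-0.42; fry p = 0.0151 with the block) and p = 0.250 for the 84 that fell at least 2-fold, of which 71 fell less in chl1-5 (0.22; fry p = 0.0334 with the block), so only these other sets passed, by fry with the block alone, and chance is not excluded for any of them. Nitrate uptake was not measured, so less nitrate in the root and less signalling were not tested against each other.

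The second pattern is ATKDSA2 lower and QQS higher in chl1-5 at both times. A mislabelled array is argued against, since the genotype labels parted all 12 arrays by over 2-fold at 4 probe sets, and the best of 48 labelings with 1 label flipped or 1 pair swapped did so at 1. A loss that takes in the named neighbours of ATKDSA2 is argued against, with 0 of 6 tested loci lower by more than 1 (log2 from -0.40 to 0.03). Loci without a named probe set were left out, so a loss that takes in only such a neighbour was not tested. Beside QQS 0 of the 10 nearest named loci were bright enough for the test. A change there that takes in neighbours cannot be told apart from a change of QQS alone. Sequence differences under the probes and differences between seed stocks of either genotype were not tested.

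The third pattern is the plastid-encoded genes, 41 of 48 lower in chl1-5 at T0 (median -0.22, camera adjusted p = 3.91e-05, but adjusted p = 0.956 with an estimated correlation). Unequal carry-over of green tissue stays open, since 13 nuclear photosynthesis genes moved by a mean of 0.00617 but by medians of 0.24, -0.0904 and -0.13 in replicate numbers 1, 2 and 3 (SE 0.117 over these). A single array stays open too, since the median was -0.05 without the wild-type T0 array of replicate 1 and -0.0201 without the chl1-5 T0 array of replicate 3, the T0 arrays with the highest actin 3'/5' ratios (15.2 and 18.4). Leaving out 1 such array unpairs its replicate number, and within replicate numbers the difference was -0.28, -0.10 and -0.23 and its median -0.15, -0.25 and -0.17 without number 1, 2 and 3, below -0.1 but by less than the SE of 0.055 in the first. A genotype effect on plastid transcripts was not tested beyond these arrays.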

How the results depend on the processing

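The settings with all 4 arrays of a replicate number left out, the exact permutations and the limits of 2-fold and 4-fold, were chosen after the results were seen, and the other settings before the data were examined. The planned check with CHL1 itself was not made, as CHL1 has no named probe set in the table used. No setting reversed the direction of any named gene or list.

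With the replicate number as a block the wild-type response called 1690 probe sets, the chl1-5 response 1415, the difference of responses 17, genotype at T0.5 60 and the mean response 3452, each with all calls made without it. The block ended no call of a gene or list. Besides the genes with a blocked value printed beside them, it added calls in chl1-5 for AT2G43890 (adjusted p = 0.0499), AT1G53620 (0.0243), AT1G57630 (0.00121), APS3 (0.0182), MCCA (0.0413) and the loci near CHL1 APA1 (0.0440) and AT1G12160 (0.0446), and in wild type for NRT1.4 (0.0368). It added AT2G48080 (0.0297) and AT1G73920 (0.0436) to the difference, and AT2G48080 (0.00241), AT1G80380 (0.00104) and AT1G64590 (0.0165) at T0.5. In the mean response it added NRT1.4, SIR, CML39 and AT1G12160, and it changed no other call of a gene named by the rules in these 6 comparisons. With only the 2 groups compared in the fit, 336 were called in chl1-5 and 2 at T0. Without the variance trend the difference had 3, and with the filter at the 60th percentile T0 had 2.

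The estimated correlation ended 22 list calls. Their medians, unchanged by it, were for the wild-type response 0.94 (pentose phosphate), 0.78 (touch), 0.0399 (glycolysis), 0.12 (plastid-encoded) and 0.25 (xyloglucan endotransglucosylases). For chl1-5 they were 1.94 (nitrate response regulators), 0.69 (pentose phosphate), 1.11 (touch), 0.28 (sugar starvation), 0.37 (plastid-encoded), 0.30 (xyloglucan endotransglucosylases) and -0.19 (autophagy). For the difference they were -0.40 (nitrate response regulators), -0.30 (pentose phosphate), -0.0933 (glycolysis) and 0.25 (plastid-encoded). Between genotypes they were -0.22 (plastid-encoded), -0.16 (NRT1/PTR) and 0.11 (autophagy) at T0, and -0.36 (nitrate response regulators), -0.28 (pentose phosphate) and -0.0940 (glycolysis) at T0.5.

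Other settings ended 9 list calls. Quantile normalization did so for autophagy (0.0883) and NRT1/PTR (-0.15) at T0 and for plastid-encoded (0.19) and touch genes (0.90) in wild type. Without a filter it was glycolysis (-0.0498) and plastid-encoded genes (0.24) in the difference and xyloglucan endotransglucosylases in wild type (0.10). With the filter at the 60th percentile it was plastid-encoded (0.12) and touch genes (0.71) in wild type.

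With 1 array or 1 replicate number left out, counts ran from 177 (without replicate number 2) to 927 (without the wild-type T0.5 array of replicate 1) in wild type, and from 74 (without replicate number 2) to 854 (without the chl1-5 T0.5 array of replicate 1) in chl1-5. They ran from 0 to 4 in the difference, 0 to 3 at T0, 2 to 21 at T0.5 and 501 to 2418 in the mean response. The median difference over probe sets that fell ran from -0.0445 to 0.14, and fry passed for them only without replicate number 3 (0.12).

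Leaving out arrays also ended list calls. In wild type the medians ran from 0.0191 to 0.13 for glycolysis, 0.00780 to 0.33 for plastid-encoded genes, 0.0704 to 1.52 for touch and 0.16 to 0.35 for xyloglucan endotransglucosylases. In chl1-5 they ran from 0.57 to 0.76 for pentose phosphate, 0.19 to 0.34 for sugar starvation, 0.34 to 1.87 for touch, 0.13 to 0.39 for xyloglucan endotransglucosylases and -0.29 to -0.16 for autophagy. In the difference they ran from -0.58 to -0.25 for the nitrate response regulators, -0.16 to -0.0390 for glycolysis and 0.10 to 0.50 for plastid-encoded genes. At T0 they ran from -0.34 to -0.0201 for plastid-encoded genes, -0.26 to -0.0811 for NRT1/PTR and 0.0343 to 0.19 for autophagy, and at T0.5 from -0.53 to -0.19 for the nitrate response regulators and -0.13 to -0.0676 for glycolysis.

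Of the 52 calls of named genes, none was lost with the block or the pseudocount, 1 each with median scaling and without the variance trend, 2 each with array weights and quantile normalization, and 3 without a filter. With the filter at the 60th percentile 39 were kept, 2 were lost and the others were not tested. Over all fits without 1 array 83 calls were lost and 235 kept, and over those without 1 replicate number 67 were lost and 89 kept. The fit of only the 2 groups compared lost 11, namely AT1G21550, AT4G17670, AT5G28610 and EXLA3 in chl1-5, AT1G57630, AT3G59850 and CYP718 in wild type, AT5G51830 at T0.5, ATKDSA2 at T0 and QQS at both times.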

Other observations

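The gene families described here were defined by gene symbols after the name table was seen and before any comparison was computed, and the families and genes singled out were chosen after their values were seen. Among expansins, cell wall proteins, members moved both ways in both genotypes. EXLA1 (log2 2.51 in wild type and 2.69 in chl1-5, SE 0.20) and EXLA2 (2.16 and 1.96, SE 0.48, dim at T0) rose, while EXPA9, EXP7 and EXPA15 (-1.05 and -0.91, SE 0.23) fell, so that of 12 tested 2 rose and 3 fell in wild type and 3 rose and 4 fell in chl1-5, and the family as a whole was not called (camera adjusted p = 0.720 and 0.551). Of 7 xyloglucan endotransglucosylases, enzymes that remodel the cell wall, XTH18 rose (1.12 and 0.95, SE 0.22). The family median was 0.25 in wild type (camera adjusted p = 0.0143, but adjusted p = 0.208 with an estimated correlation) and 0.30 in chl1-5 (0.0353, but adjusted p = 0.381 with an estimated correlation).

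Several regulators and transporters answered nitrate in both genotypes. WRKY22 rose by 1.72 in wild type and 2.18 in chl1-5 (SE 0.29), BZIP53 by 1.24 and 0.99 (SE 0.23), the vacuolar sugar transporter SWEET16 by 0.92 and 1.06 (SE 0.20) and AT1G59740 of the NRT1/PTR family by 1.49 and 1.17 (SE 0.27). GTR1, a glucosinolate transporter of that family, rose by 1.14 in chl1-5 and stood at 0.92 in wild type (SE 0.25, adjusted p = 0.0537, 0.00793 with the replicate block). UGT76C2, which glucosylates cytokinins, fell by 1.06 in wild type and 0.69 in chl1-5 (SE 0.16), and the flavonoid glucosyltransferase UGT78D2 fell by 0.53 and 0.50 (SE 0.12). WRKY6 fell by 0.76 and the dehydrin gene LTI30 rose by 0.78 in wild type. bZIP58 rose by 1.49 in wild type and stood at 0.43 in chl1-5 (SE 0.20), a difference of -1.06 that did not pass (adjusted p = 1.00, 0.135 with the block). Beyond the naming rule, MDH (AT3G47520), a malate dehydrogenase, was lower in chl1-5 at T0.5 by 0.63 (log2 -0.63, adjusted p = 0.0343) and AT3G18560 by 0.82 (log2 -0.82, adjusted p = 0.0306).

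Among 125 list tests 23 were called with the preset correlation, and 1 of them, the nitrate response regulators in wild type, also with the estimated one. Of the 6 glycolysis enzymes tested PGM changed, and GAPC2 passed only with the replicate block (0.22 in wild type, adjusted p = 0.276, 0.0392 with the block, and 0.23 in chl1-5, adjusted p = 0.289, 0.0373 with the block). The list was called in wild type (median 0.04, camera adjusted p = 0.0143, but adjusted p = 0.118 with an estimated correlation) and between genotypes at T0.5 (median -0.09, camera adjusted p = 0.00123, but adjusted p = 0.0577 with an estimated correlation). The plastid-encoded genes had a median response of 0.12 in wild type (camera adjusted p = 0.0344, but adjusted p = 0.884 with an estimated correlation) and 0.37 in chl1-5 (camera adjusted p = 8.84e-07, but adjusted p = 0.515 with an estimated correlation), where 1 of 48, clpP, rose over all genes, 0 adjusted over the list alone and 7 with the replicate block. By replicate number their genotype difference at T0 was -0.28, -0.10 and -0.23 and at T0.5 0.26, -0.38 and 0.22. The 10 autophagy genes had a median of -0.19 in the chl1-5 response (camera adjusted p = 0.0317, but adjusted p = 0.659 with an estimated correlation) and 0.11 between genotypes at T0 (camera adjusted p = 0.0146, but adjusted p = 0.956 with an estimated correlation). The 8 NRT1/PTR genes had a median of -0.16 between genotypes at T0 (camera adjusted p = 0.0344, but adjusted p = 0.449 with an estimated correlation).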
